A study of Mus musculus with 6 samples.

How the data were processed

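RNA-seq libraries were measured from 6 samples of mouse inner ear organoids, 3-dimensional cultures of wild-type epithelial cells per the labels. The 3 PD samples were grown with 1 µM PD0325901, an inhibitor of the kinases MEK1 and MEK2, and the 3 DMSO samples with the same volume of the solvent, each for 10 days. Per the labels' protocols, the low-attachment cultures held EGF at 20 ng/mL, bFGF at 10 ng/mL, IGF at 50 ng/mL and the GSK3 inhibitor CHIR99021 at 3 µM, and the medium was renewed every 2 days. Libraries were made from 2 µg of total RNA with a stranded mRNA kit, per the labels. The labels do not say whether the samples of a group are separate cultures, so p-values measure only the spread between these samples, which may be technical.

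The submitters' processing notes name Trimmomatic, HISAT2, HTSeq and DESeq2 and the mouse build mm10; versions, roles, annotation and strand setting are not given in the sources used here. The deposited table holds a normalized signal per gene and sample, rounded to 2 decimals, and per the file headers no scale is stated. These values are not read counts, so the depth of the libraries is unknown and no counting interval or floor is given. The authors also deposited their mean of each group, a fold of PD over control, its log2 value, a p-value and an adjusted p-value for each gene. All 4994 genes of the table carry a fold of at least 1.5 in either direction and an adjusted p of at most 0.0499 in the authors' deposited table, where 2340 genes were higher and 2654 lower in PD. The table is therefore a selection made by the authors on these same samples. Counts given here are counts among listed genes, never of the genome, and are not independent evidence of a difference. The ratio of mean values and the authors' fold pointed opposite ways in 33 genes. Over the 1666 genes with a mean of at least 10 in both groups, the log2 ratio of means exceeded the authors' log2 fold by a median of 0.04.

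Columns were matched to samples by their names, and 0 columns of per-sample values were left without a sample. Of the gene identifiers, 4988 were found in GENCODE M21, an annotation of GRCm38, the same assembly as mm10, and 6 were not. Coordinates are 1-based on that build. The table has 4325 protein coding genes and 744 rows with a predicted, Rik or pseudogene name or biotype. Where 2 rows carried the same symbol, which happened for 2 symbols, the row with the higher mean was used for the gene lists.

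The design fixed before the data were examined was a quasi-likelihood test on read counts. Because the values are normalized, limma 3.58.1 in R 4.3.3 was used instead, with a trend of the spread on the level, on log2(value + 1), without a filter on low values, over all 6 samples and without a block. P-values were adjusted by the Benjamini-Hochberg method over the 4994 genes, and genes with an adjusted p under 0.05 were called. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Errors of group means are SD and errors of log2 differences are SE, with n = 3 per group. On simulated values for the 4994 genes of this comparison, 50 genes were changed at each fold, drawn among genes with a DMSO level of at least 5. The procedure recovered 68% of genes changed 1.5-fold, 96% at 2-fold, and 98% at both 4-fold and 8-fold, and called 6 of 4794 unchanged genes. The simulation changed 200 genes whereas 4770 real genes were called, so these rates do not carry over to the real comparison or to lower values.

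Gene lists were fixed before the data were examined: 29 lists of pathways, inner ear cell types and other cell types the cultures could hold. The 27 lists with at least 5 listed genes were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with the other listed genes, and adjusted over the 27 lists. The lists were tested again with an estimated correlation and with fry, a rotation test that asks whether a list moves on balance without a comparison to other genes. The genes named are those a rule fixed beforehand selects: the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 in a group, groups that do not overlap and no predicted or pseudogene name; up to 4 genes per list with the smallest adjusted p; and a set of MEK pathway, hair cell and cell cycle genes. Of that set, Map2k2, Mapk3, Atoh1, Gfi1, Myo7a, Myo6, Hes5, Axin2 and Cdkn1b are not analysed here. Some genes that the rule selects are not reported here. Other genes named were chosen after their values were seen, and the text says so.

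Alternatives covered scaling, pseudocounts, filters, the trend, a replicate block and leaving out each sample in turn. Pseudogene transcripts were aligned to coding transcripts with blastn 2.17.0, at an identity of at least 95% over at least 80% of the length. Other tests used Python 3.11.15, scipy 1.17.1 and pandas 2.3.3, and the search for single-library jumps found 40 of 40 jumps planted in simulated values and 0 others. The planted jumps were larger than the search rule requires, and the simulated spread was small and not the genes' own. That result checks only that the search runs as written.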

Results

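Gene expression was measured in mouse inner ear organoids cultured for 10 days with the MEK inhibitor PD0325901 (PD, n = 3) or with its solvent (DMSO, n = 3). The stated purpose was the mechanism by which the inhibitor might promote hair cells, the sensory cells of the inner ear; hair cell number is not measured here. Values of the 4994 genes the authors selected summed to between 289255 and 293278 in the DMSO libraries and between 290560 and 296997 in the PD libraries. These sums are not depths, which are unknown. Across these genes the log2 values correlated at 0.983 to 0.988 within groups and at 0.837 to 0.843 between groups, although genes are not independent replicates and were selected for differing.

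In PD organoids, 17 of 18 listed targets of the ERK kinases fell and 1 rose, all 22 genes of glycolysis and the hypoxia response fell, and of the cell cycle genes all 27 of mitosis and 23 of 24 of S phase fell, with 1 not called. These lists were lower by camera at its preset correlation, and none kept that call with an estimated one (adjusted p = 0.57 with an estimated correlation for each). Dusp6, the phosphatase that limits ERK signalling, averaged 149.8 ± 3.58 in DMSO and 12.3 ± 1.33 in PD (SD, n = 3). Glycolytic Gpi1 fell from 1537 ± 84.2 to 210.5 ± 15.3, and the proliferation marker Mki67 fell from 107 ± 6.73 to 21.1 ± 2.67 (SD, n = 3). Of the tectorial and otolithic matrix genes 12 of 14 rose, among them Epyc, a small proteoglycan, from 999 ± 66.9 to 7259 ± 190.3 (SD, n = 3). Listed hair cell genes moved both ways, and several of those that rose had values under 1. Many of the hair cell genes fixed beforehand are not listed. Of 13 mitochondrially encoded protein genes fixed beforehand as a sign of RNA quality, 5 are listed and 8 are not. The 5 made up 8.5% to 9.89% of the summed values in the DMSO libraries and 14.9% to 15.3% in the PD libraries. These are shares of the listed genes' values, not of a whole library. They are uncertain for mt-Nd4l, which has a nearly identical listed pseudogene. This sign separated the groups along with most genes of the gene groups described here. Because the authors' selection kept only genes that differ, that separation of the 5 was fixed in advance.

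By limma, 4770 of the 4994 listed genes changed at the adjusted threshold, 2220 higher and 2550 lower in PD. A total of 4773 had an unadjusted p under 0.05, and 224 were not called. Values of the groups did not overlap in 4754 genes, where chance gives 10% of genes. Since the authors chose the table on these samples, these counts are not independent evidence. In 1 gene, Gm16867, named for this reason after its values were seen, the call opposed the direction of the authors' deposited table, with 4.86 ± 0.813 in DMSO and 7.47 ± 0.696 in PD.

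The largest rise by log2 difference on log2(value + 1), among genes the naming rule allows, was that of Rgcc (ENSMUSG00000022018, chromosome 14, 79288756 to 79301645, minus strand), a regulator of the cell cycle. It went from 3.04 ± 0.938 to 139 ± 16.3, a log2 difference of 5.14 ± 0.17 (SE, limma adjusted p = 6.64e-07). The cartilage matrix gene Matn1 went from 0.080 ± 0.0985 to 20.3 ± 3.76, Smoc2 from 13.4 ± 1.8 to 236 ± 21.3, the fibrillar collagen gene Col27a1 from 34.6 ± 1.69 to 424 ± 45.2, and the guidance ligand gene Slit3 from 6.25 ± 0.536 to 85.3 ± 3.32. Rspo2, which encodes an enhancer of Wnt signalling, rose from 4.07 ± 0.395 to 69.1 ± 4.36. The cytoskeletal adaptor genes Tns3 and Ablim1 rose by 3.78 and 3.47 on the log2 scale. Pamr1, Sned1, Fam3b and Bpifb5 completed the 12, at log2 differences of 3.63, 3.62, 3.53 and 3.49.

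The largest fall by log2 difference on log2(value + 1), among genes the naming rule allows, was that of Ndrg1 (ENSMUSG00000005125, chromosome 15, 66929318 to 66969640, minus strand), a hypoxia-inducible gene. It went from 205 ± 39.4 to 3.7 ± 0.264, a log2 difference of -5.44 ± 0.14 (SE, limma adjusted p = 2.82e-07). By the ratio of the DMSO mean over the PD mean, genes with PD means under 1 fell further, such as Adm at 971 and Rgs4 at 199 against 55.4 for Ndrg1. The hypoxia-inducible genes Adm, Egln3 and Car9 were also among the 12 largest falls, at log2 differences of -4.69, -4.40 and -4.23, as was the enolase gene Eno2 at -4.40. Ngfr, a neurotrophin receptor gene used as a marker of pillar cells and other supporting cells, went from 28.7 ± 1.5 to 0.193 ± 0.121. Aire went from 114 ± 8.72 to 2.5 ± 1.55, Mgarp from 46.5 ± 6.63 to 0.54 ± 0.342, and Rgs4 from 23.9 ± 6.76 to 0.12 ± 0.0781. Exoc3l4 and Cldn24 fell with log2 differences of -4.86 and -4.62. Zfp652os spread widely, at 70.6 ± 35.1 in DMSO and at 0, 21.32 and 0 in the PD libraries, and because its name marks an opposite-strand transcript and the strand setting of the counting is not stated, its reads cannot be told from those of its partner.

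Among ERK targets and feedback genes, 17 of the 18 listed genes fell and 1, Myc, rose, from 4.15 ± 0.387 to 7.44 ± 1.39; Myc was named after its values were seen. All 18 were also called when adjusted over the list alone. The transcription factor genes Etv4 and Etv5 fell from 105 ± 1.79 to 7.21 ± 2.47 and from 126 ± 5.02 to 12.8 ± 2.61. The immediate early gene Egr1 fell from 12 ± 1.47 to 0.277 ± 0.10, and the feedback inhibitor genes Spry2 and Spry4 fell with log2 differences of -2.81 and -2.50. Dusp6 (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489, plus strand) had a log2 difference of -3.50 ± 0.08 (SE; limma adjusted p = 2.00e-07). Map2k1, which encodes MEK1, a target of the inhibitor, fell from 231 ± 6.33 to 79.3 ± 1.61. Against the other listed genes the list was lower by camera (adjusted p = 0.000177), but not with an estimated correlation (adjusted p = 0.57 with an estimated correlation).

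**Figure D1:**
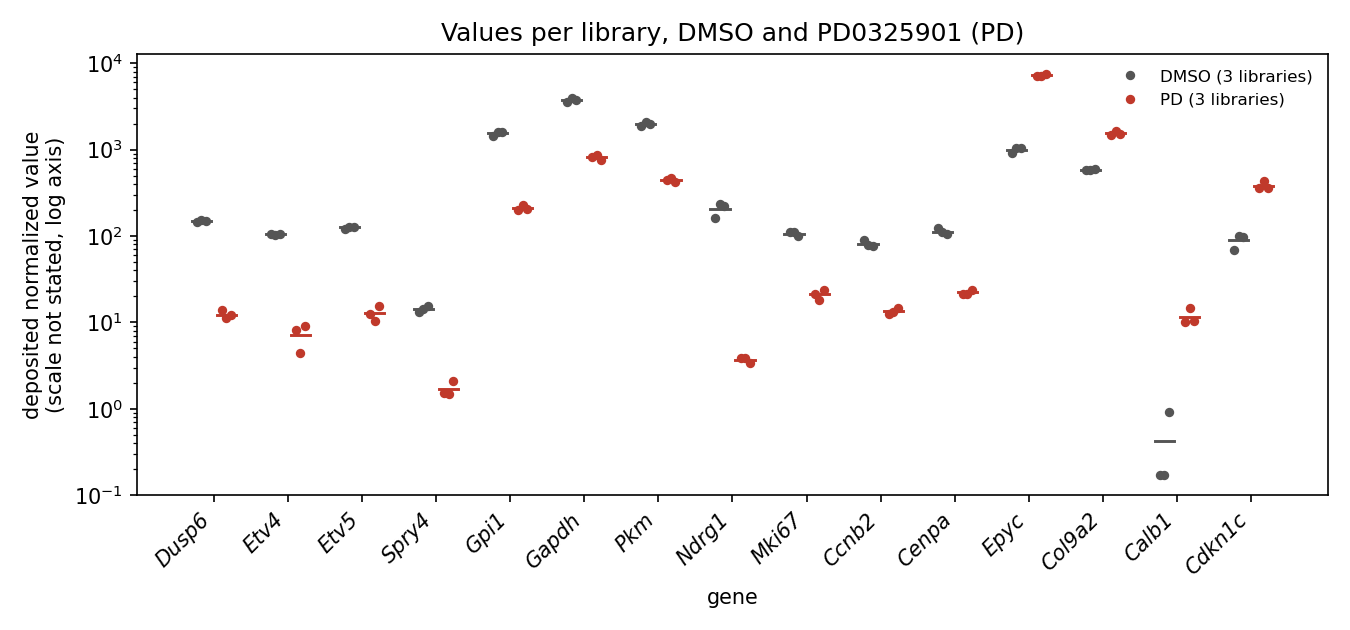
Deposited normalized values (log axis, scale not stated) of 15 named genes in the 3 DMSO and 3 PD libraries; points are libraries and bars are group means. Dusp6, Gpi1 and Mki67 lie lower in every PD library than in any DMSO library, and Epyc lies higher.

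All 22 genes of the glycolysis and hypoxia list were listed and all fell, also when adjusted over the list alone, with a median log2 difference of -2.73. Pkm, which encodes pyruvate kinase, fell from 1967 ± 113 to 447 ± 22.2. Gapdh fell from 3753 ± 172 to 809 ± 52.7, a value uncertain in its share of reads, because 9 listed pseudogenes are nearly identical to it. The list was lower by camera (adjusted p = 9.44e-08; adjusted p = 0.57 with an estimated correlation).

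Of the 27 listed G2 and mitosis genes, 27 fell, with a median log2 difference of -1.98. Of the 24 listed genes of S phase and replication 23 fell and 1, E2f1, named after its values were seen, was not called, at 6.22 ± 0.903 and 6.16 ± 2.81. Counts adjusted over the list alone were 27 and 23. By the authors' folds, on which the genes were selected, all 24 S phase genes were lower. Ccnb1 and Ccnb2, which encode mitotic cyclins, fell from 107 ± 2.73 to 23.1 ± 2.28 and from 81.7 ± 6.84 to 13.5 ± 1.22. The centromere histone gene Cenpa fell with a log2 difference of -2.29, and Cdc20 with -1.85. In S phase, the log2 differences were -1.63 for Chaf1b, -1.65 for Mcm3, -1.48 for Rfc4 and -1.24 for Rrm1. The camera adjusted p was 9.44e-08 for mitosis and 0.000171 for S phase (adjusted p = 0.57 with an estimated correlation for each). Among cell cycle inhibitors and p53 targets 2 rose and 9 fell, all 11 also called when adjusted over the list alone, without a camera call (adjusted p = 0.221). Cdkn1c, which encodes the inhibitor p57, rose from 89.2 ± 17.4 to 382 ± 42.4, and Gadd45b and Cdkn2c fell with log2 differences of -1.54 and -1.15.

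Listed hair cell genes gave no single direction. Of the hair cell genes fixed beforehand, 12 of 24 channel, synapse and calcium genes are listed. So are 10 of 28 bundle and cytoskeleton genes and 6 of 20 transcription and early identity genes. The rest are not listed, so the counts below do not cover the fixed lists as a whole. Of the channel, synapse and calcium genes, 8 of 12 rose, 1 fell and 3 were not called (9 called when adjusted over the list alone). By the authors' folds, on which the genes were selected, 11 were higher and 1 lower. The list was higher by camera (adjusted p = 0.0404, and adjusted p = 0.57 with an estimated correlation). Restricted to genes with values of at least 1 in at least 3 samples, the camera adjusted p was 0.28, and it was 0.0543 with the 10 highest genes left out. Calb1, a calcium buffer gene, rose from 0.42 ± 0.433 to 11.6 ± 2.57, the potassium channel gene Kcnma1 from 1.29 ± 0.184 to 4.81 ± 0.785, and Slc7a14 from 0.040 ± 0.0173 to 0.933 ± 0.155. Tmc1, a component of the mechanotransduction channel, fell from 4.0 ± 0.266 to 0.627 ± 0.272. Of the 3 not called, named after their values were seen, Tmie averaged 3.31 ± 1.41 and 5.38 ± 1.08, Chrna10 0.0367 ± 0.0351 and 1.03 ± 1.33, and Cacna1d stood at 90.45 in PD replicate 2 and at no more than 11.21 in the other PD libraries. Of the bundle and cytoskeleton genes 3 rose, 5 fell and 2 were not called (8 called over the list alone), with camera adjusted p = 0.486. Those 2, named after their values were seen, were Triobp, at 58.9 ± 4.33 and 57.2 ± 3.64, and Whrn, at 59.43 in DMSO replicate 3 and at most 3.76 in the other DMSO libraries. By the authors' folds 3 of the bundle and cytoskeleton genes were higher and 7 lower. Espn, the bundle crosslinker, fell from 32.3 ± 4.62 to 2.46 ± 0.168, Ush1c from 181 ± 22.5 to 29.1 ± 2.04 and Cdh23 from 3.58 ± 0.576 to 0.40 ± 0.191, whereas Ptprq rose from 0.59 ± 0.0954 to 6.01 ± 0.882. Of the transcription and early identity genes 2 rose and 4 fell (6 over the list alone; camera adjusted p = 0.631). Pou4f3 (ENSMUSG00000024497, chromosome 18, 42394539 to 42397249, plus strand), a transcription factor of hair cells, rose from 0.117 ± 0.0681 to 0.617 ± 0.225, so its level stayed under 1. Ccer2 rose from 2.92 ± 0.488 to 10.3 ± 1.54, and Rasd2 and Jag2 fell with log2 differences of -1.73 and -1.36.

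Of 14 listed tectorial and otolithic matrix genes, 12 rose and 2 fell, all 14 also when adjusted over the list alone, and the list was higher by camera (adjusted p = 0.0105; adjusted p = 0.57 with an estimated correlation). Epyc had a log2 difference of 2.86 ± 0.06 (SE; limma adjusted p = 1.52e-07), Col9a2 rose from 583 ± 10.4 to 1554 ± 81.9 and Itih5 from 12.5 ± 0.462 to 50.2 ± 0.54. Otol1, which encodes the otoconial matrix protein otolin, fell from 1690.2 ± 167 to 220.1 ± 1.59; the other that fell, Otog, went from 169 ± 18.6 to 46.1 ± 5.93 and was named after its values were seen. Fibroblast and mesenchyme markers, which share 1 gene with this list (Dcn, named after its values were seen), gave 9 higher, 4 lower and 2 not called.

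Supporting cell and prosensory genes split into 5 higher and 8 lower (camera adjusted p = 0.68), and Notch pathway genes into 3 higher and 7 lower (0.381); all 13 and all 10 were also called over the list alone. Lgr5 and Lgr6, receptors of supporting cell progenitors, fell from 22.5 ± 0.841 to 7.52 ± 1.32 and from 39.4 ± 0.903 to 8.13 ± 0.31. The log2 difference was -1.47 for Isl1, -0.70 for the progenitor factor gene Sox2 and 1.11 for Fam107a. The Notch effector genes Hey1, Hey2 and Hes1 fell with log2 differences of -2.73, -3.75 and -1.42, and the ligand gene Jag1 with -0.76, whereas Maml2 rose by 0.85. Wnt targets gave 7 higher and 6 lower (13 over the list alone; camera adjusted p = 0.582), with Nkd1 up from 18.3 ± 1.45 to 60.1 ± 5.98, Notum and Apcdd1 up by 1.71 and 1.68, and Cd44 down from 82.8 ± 6.01 to 26.9 ± 5.25. Otic epithelium genes gave 2 higher, 5 lower and 1 not called (7 over the list alone; camera adjusted p = 0.294). The keratin genes Krt8 and Krt18 fell from 254 ± 2.16 to 83 ± 9.43 and from 484 ± 20.0 to 89.1 ± 11.9, and the log2 differences of the claudin gene Cldn6 and the cadherin gene Cdh1 were -1.31 and 1.07.

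Growth factor receptor and ligand genes gave 10 higher and 4 lower (14 over the list alone; camera adjusted p = 0.0891). Igf1 rose from 1.58 ± 0.391 to 26.1 ± 1.41, Egf from 4.0 ± 0.878 to 22.4 ± 2.9, Met from 21.2 ± 0.936 to 63.4 ± 3.47 and Fgfr1 from 49.9 ± 3.9 to 122 ± 8.97. All 8 listed genes of cholesterol synthesis fell, also over the list alone (camera adjusted p = 0.0163; adjusted p = 0.57 with an estimated correlation), with log2 differences of -1.52 for Insig1, -0.88 for Fdps, -1.06 for Ebp and -0.94 for Dhcr7. Stress and unfolded protein response genes gave 9 higher and 3 lower (12 over the list alone; camera adjusted p = 0.0614), with the serine synthesis genes Psat1 and Phgdh up by 1.47 and 0.79, Pdia4 up by 0.76 and Xbp1 at a log2 difference of -0.84. YAP and TEAD targets gave 4 higher, 3 lower and 1 not called (7 over the list alone; camera adjusted p = 0.68), with Amotl2 at 1.21, Fjx1 at 1.95, Axl at -1.56 and Ankrd1 at -1.18. Interferon and antigen presentation genes gave 2 higher and 4 lower (6 over the list alone; camera adjusted p = 0.479), with H2-K1 at -1.40, Bst2 at -1.29, Oasl2 at -1.48 and Mx1 at 1.74.

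**Figure D2:**
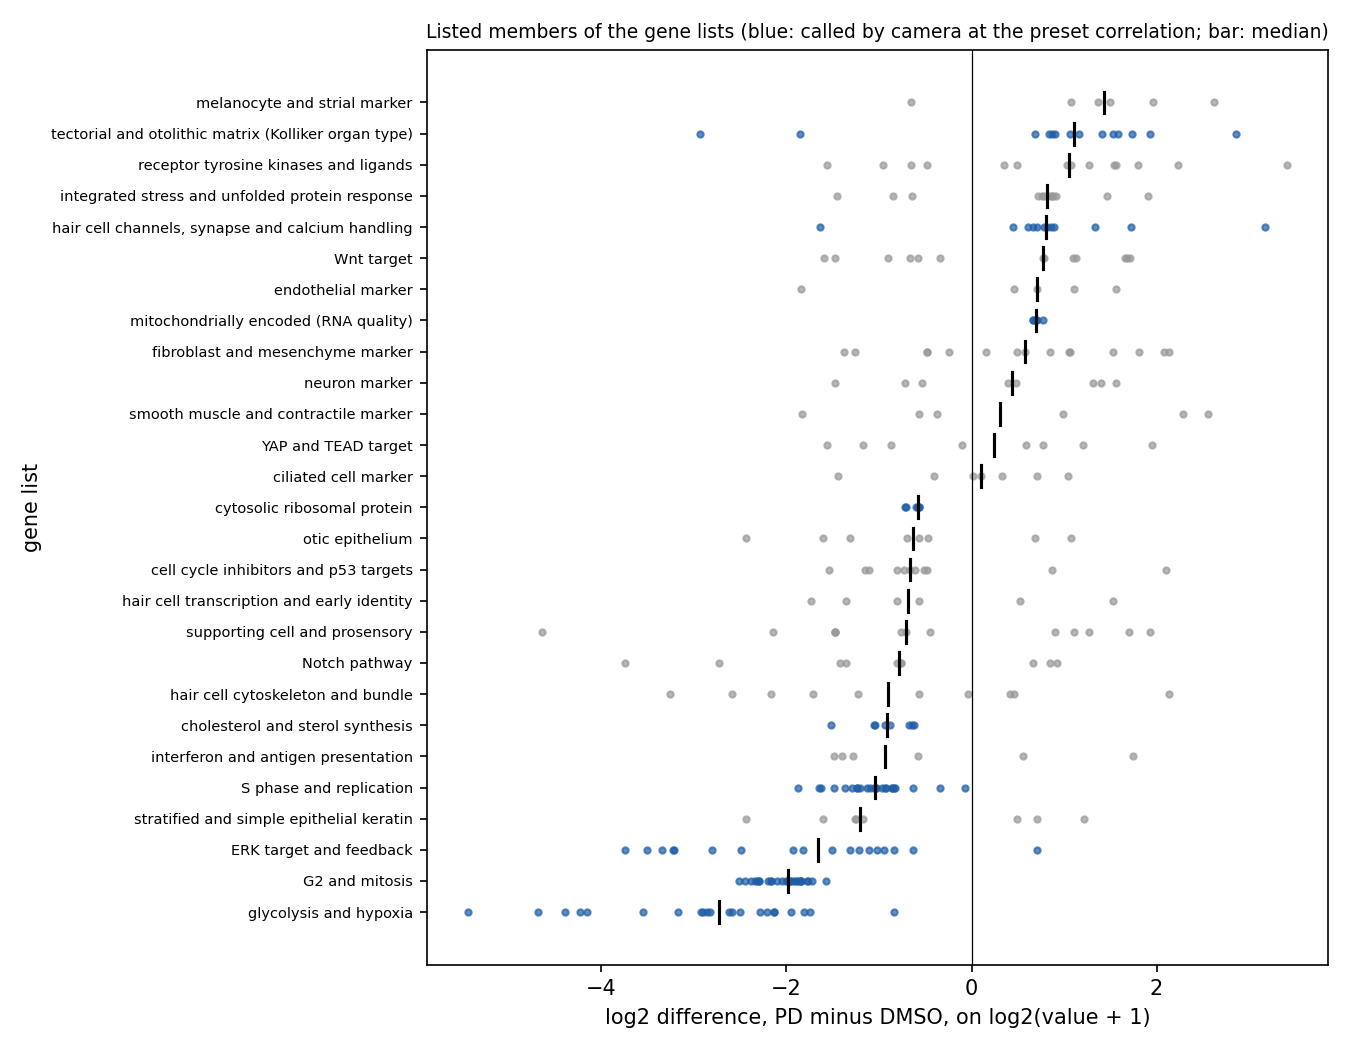
Log2 difference of PD minus DMSO (horizontal axis, on log2 of value + 1) for the listed members of the 27 gene lists (vertical axis). Points are genes, black bars are list medians, and blue marks the 9 lists called by camera at the preset correlation. None of the 9 kept its call with an estimated correlation. The median was -2.73 for glycolysis and hypoxia and -1.98 for G2 and mitosis.

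Markers of other cell types moved with the treatment in both directions. Fibroblast and mesenchyme markers gave 9 higher, 4 lower and 2 not called (13 over the list alone; camera adjusted p = 0.17), with Lum up from 619 ± 42 to 1794 ± 132 and Vim, Tbx18 and Pou3f4 up by 0.85, 2.08 and 2.13. Smooth muscle markers gave 3 higher and 3 lower (6 over the list alone; 0.631 by camera, adjusted), with Myl9 at 2.56, Mylk at 2.29, Tagln at 0.99 and Tpm2 at -1.83. Neuron markers gave 5 higher and 3 lower (8 over the list alone; camera adjusted p = 0.482); Syt1, Dcx and Gap43 rose to 2.29 ± 0.0985, 1.98 ± 0.155 and 2.42 ± 0.255 in PD. Endothelial markers gave 4 higher and 1 lower (5 over the list alone; camera adjusted p = 0.298), with Tek at -1.84, Kdr at 1.56, Emcn at 1.11 and Cdh5 at 0.71. Strial and melanocyte markers gave 5 higher and 1 lower (6 over the list alone; camera adjusted p = 0.0614), and Slc12a2, Slc26a4, Lrp2 and Cldn11 rose by 1.49, 1.36, 2.62 and 1.96. Keratins gave 3 higher and 5 lower (8 over the list alone; camera adjusted p = 0.381), with Ivl at -1.24 and Sfn at -1.26. Ciliated cell markers gave 2 higher, 2 lower and 3 not called (4 over the list alone; camera adjusted p = 0.793), with Rsph1 at -1.44, Foxj1 at -0.41, Dnah9 at 0.71 and Cfap44 at 1.04. In the lists too short to test, the glial genes Pmp22 and Prx rose by 0.61 and 0.66, and the leukocyte gene Ptprc was listed at 0 in every DMSO library and at 0.21, 0.21 and 0.06 in PD.

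Of the 13 mitochondrially encoded protein genes fixed as the sign of RNA quality, the 5 listed rose, 5 also over the list alone. Of 26 cytosolic ribosomal protein genes, the 7 listed fell, 7 also over the list alone. The mitochondrial transfer RNA gene mt-Tp, outside the mitochondrial list and named after its values were seen, fell from 277 ± 13.8 to 93.6 ± 1.49. Camera called both lists (adjusted p = 0.037 and 0.0163; adjusted p = 0.57 with an estimated correlation for each), and without a trend the mitochondrial list had adjusted p = 0.0578. The mt-Cytb value went from 7813 ± 593 to 13298 ± 244, and mt-Nd4, mt-Nd5 and mt-Nd4l rose by 0.70, 0.66 and 0.71. The mt-Nd4l value is uncertain in its share of reads, because the listed pseudogene Gm10222 aligns to it at 100% identity. Gm10222, named after its values were seen, rose by 0.70. Rps19 and Rpl11 had log2 differences of -0.72 and -0.56. Leaving out the 10 highest genes, which include all 5 genes of the mitochondrial list, shifted the log2 differences of the other genes by a median of 0.11, so the mitochondrial list has no value under that setting; the ribosomal list stayed lower (camera adjusted p = 0.0205).

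Camera at the preset correlation called 9 of the 27 lists, and none of the 9 kept its call with an estimated correlation, where 0 lists were called and every adjusted p of these 9 was 0.57. The fry test called 26, but all listed genes were selected for differing on these samples, so that count is not independent evidence. With the estimated correlation 0 lists had an unadjusted p under 0.05 by camera, against 12 at the preset one. The other 9 of the 10 ways to split the 6 samples into groups of 3 called between 4 and 8 lists at the preset correlation. They called 0 genes by limma, with 6 to 16 genes at an unadjusted p under 0.05. Each of them mixes PD and DMSO samples in both groups, and the genes were selected for differing between PD and DMSO. Their counts are therefore not what chance alone gives.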

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

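Scaling, pseudocount, value filter, coding genes alone and trend settings were chosen after seeing the data; the other settings were planned. The count of changed genes was 4770 and ran from 3931 with a fold of at least 1.5 to 4803 with a pseudocount of 0.1; 0 results reversed. Leaving out 1 sample at a time gave 4626 to 4660 changed genes and 9 to 10 called lists. The replicate block gave 4761 genes and 9 lists; same-numbered samples correlated in their deviations at -0.032, -0.005 and -0.001, so they share only a number. Gene lists called fell from 9 to 0 with an estimated correlation and were 26 by fry, whose question needs no comparison with other genes. Every listed gene was selected for differing on these samples, so the fry count was largely fixed in advance. The cause of the 0 was not tested. Of 139 named genes, 1 lost its call under some setting (Ptprc). The list count was 7 with the 10 highest genes left out, where the mitochondrial list has no genes left to test. Not run, because they need read counts: median-of-ratios factors, the count filters as planned, the DESeq2 Wald test and voom; total-count scaling and the removal of the 10 most abundant genes were adapted to the values. Depth is unknown, so genes near 0 cannot be separated from counting noise.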

Other observations

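Cartilage-type matrix genes rose, on a list drawn up after the strongest rises had been seen, so its count is not independent evidence. Of 20 such genes, 14 were listed and 14 rose (limma), 0 fell, with a median log2 difference of 2.22; of the other called genes 2206 rose and 2550 fell (Fisher's exact test, two-sided, p = 2.2e-05 across genes, which are not independent). Cnmd, which encodes the cartilage protein chondromodulin, went from 306 ± 9.35 to 2517 ± 120.1, Col11a2 from 111 ± 7.83 to 942 ± 12.9, and Mia from 619 ± 35.2 to 2022 ± 282 (SD, n = 3). Markers of another cell type moved alongside: of 15 listed fibroblast and mesenchyme markers, none of them on the cartilage list, 9 rose, 4 fell and 2 were not called (camera adjusted p = 0.17), with log2 differences of 2.13 for Pou3f4, 2.08 for Tbx18, 1.53 for Lum, 1.06 for Dcn and -1.38 for Fn1. A lysosome list, also drawn up after some of its members had been seen, had 14 listed genes of 36, of which 13 rose and 1 fell (p = 0.00053 by the same exact test). Lamp1, a lysosomal membrane protein gene, went from 138 ± 6.78 to 389 ± 23.7 and the protease gene Ctsd from 142 ± 10.9 to 329 ± 9.44; Ctsh fell, from 8.17 ± 1.03 to 5.46 ± 1.51. The mitochondrial sign of RNA quality also differed between the groups, at 8.5% to 9.89% of summed values in DMSO and 14.9% to 15.3% in PD. It rests on the 5 of 13 fixed genes that the authors' selection kept. Apart from Pou3f4, Tbx18 and Lum, the genes named here were chosen after their values were seen.

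Of the tests below, those on scaling, cycling cells, oxygen, reads that jumped and pseudogenes were chosen after the result was seen; the tests on transcript length and on other splits were not. Of the 10 splits of the 6 samples, 1, the real one, gave as many changed genes (4770, highest other 0) and 1 gave as many called lists (9, highest other 8). With 10 splits the share cannot go under 0.1, so the splits are too few to decide on chance. The other splits also mix PD and DMSO samples of genes selected for differing, so their lack of called genes was largely fixed in advance.

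The 22 glycolysis and hypoxia genes all fell, with a median log2 difference of -2.73 and an SD of 1.11 across genes. That fall exceeded the shift under every scaling alternative, none of which moved a gene by more than 0.131. The alternatives only rescale normalized values of selected genes, so they cannot test how the libraries were first scaled. Fewer cycling cells alone would lower the list by at most as much as the mitosis genes (median -1.98); the list's median differed from theirs by -0.74 (permutation p = 3e-05, one-sided, over genes), less than the SD of its members, and its 15 glycolytic and glucose uptake members by -0.31 (permutation p = 0.0402) and, on the folds of the authors' deposited table, by -0.4 (permutation p = 0.00361), also within their SDs of 0.74 and 0.77. The requirement that the difference exceed this SD was added after these values were seen, and without it they would argue against this explanation; with it the explanation stays open for the list and these members, and is argued against for the 7 other members, Egln3, Car9, Ndrg1, Adm and, named after their values were seen, Vegfa, Bnip3 and Ankrd37, whose median of -4.23 differed by -2.24 (permutation p = 7e-05). In a further list of 26 hypoxia-inducible genes outside glycolysis, written before their values were looked at, 24 were listed and 100% of these were lower in PD, against 51.1% of all listed genes, with a median of -1.60, smaller than the mitosis fall, and a range from -3.69 (P4ha2) to -0.43 (Kdm4b), both named after their values were seen. Less oxygen limitation in the treated cultures is a candidate explanation, as a hypothesis, but fewer cycling cells stay open for that list too, and a direct effect of MEK inhibition was not tested, since nothing here measures oxygen or organoid size; RNA quality, whose mitochondrial sign moved with the groups, was not weighed.

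In 42 genes the value of 1 library was at least 5 and at least 5 times each other library of its group, and 40 of them were tested; in the other 2, Zfp652os and 4930412L05Rik (the latter named after its values were seen), a mean at 0 leaves no ratio. The authors' fold lay nearer to the ratio of means without that library in 80% of the 40 (exact 95% interval 64.4 to 90.9), with a median distance of 0.31 against 2.29 on the log2 scale, which argues against reads that jumped as the source in most of the genes tested; genes whose reads did jump may have been left out of the selected table. Short transcripts, which inflate length-normalized values, were not more frequent: 9 of the 36 coding genes among the 40 had a transcript under 400 nt, against 1126 of 4289 others (odds ratio 0.936, exact interval 0.386 to 2.06), too wide to exclude them. The cause of the jumps stays open. Whrn (59.43 in DMSO replicate 3, at most 3.76 in the other DMSO libraries) and Slc16a3 (90.95 in PD replicate 3, at most 6.57 in the others) are examples chosen after their values were seen.

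Of 125 pseudogene rows, 37 had a nearly identical coding gene in the table, and 33 of these changed in its direction (Spearman rho 0.62 across pairs, above the largest of 10000 random pairings, 0.58). That meets the bound set for shared reads, but 9 pairs have Gapdh as the parent and are not independent. With 1 value per parent, a step chosen after the pairs had been seen, rho was 0.49 over 28 parents (permutation p = 0.0043), below the largest random pairing of 0.64. Shared reads are thus a candidate explanation that these pairs cannot settle, and the pseudogene rows are best read together with their parents.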
